A study of Mus musculus with 6 samples.

How the data were processed

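RNA from the small intestine of mice was measured by total RNA sequencing in 6 libraries, 3 labelled GFP control and 3 labelled PKCzeta overexpression. Per the labels' protocols, RNA was extracted with a silica column kit, ribosomal RNA was depleted, and libraries were made with a kit that keeps the strand of each transcript. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2 and StringTie were used with the mouse build mm10, with no versions. Which program produced the read counts, and whether it used the strand, is not given in the sources used here.

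The authors deposited 1 table of 45777 genes, each with an Entrez gene ID, a symbol and a biotype. Per the file headers, the deposited table gives each library a read count, an FPKM value and a TPM value per gene. The deposited counts are whole numbers with no normalisation. The deposited FPKM values are counts scaled to transcript length and library size, and were not used in any test. The deposited TPM values are scaled to length and then to a fixed sum per library, and were used only in an alternative test. Total counts ran from 77573133 to 93742978 per library, and the biological coefficient of variation in edgeR was 0.354, so counting error matters mainly for genes far below 1 CPM. The RefSeq gene table used for positions is of the same build (GRCm38, the assembly that mm10 names), and 45679 of the 45777 gene IDs were matched to it. Positions count from 1.

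Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 18456, libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion compared the groups, two-sided. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM, read counts scaled to a common library size, after TMM scaling, given as mean ± SD with n = 3, and log2 fold changes are PKCzeta minus GFP with their standard error (SE). For Prkcz and Slc2a1 an exact two-sided permutation test of log2 CPM, with a prior count of 2, was added. The labels do not say outright that each library is a separate animal, and p-values then measure only the spread between these samples.

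Groups of genes were tested with camera in limma 3.58.1 over 49 lists, which hold pathways, gene families, intestinal regions and markers of the cell types that a piece of small intestine or its surroundings could hold. Of 1002 list entries, 999 were found in the table, and each list had at least 5 tested members. The correlation between genes was preset at 0.01, and p-values were adjusted over the 49 lists. Beside it stand camera with a correlation estimated for each list, and fry, which tests whether the genes of a list move one way on balance. A list's score in a library is the mean, over its members, of the log2 CPM deviation from the gene's mean over the 6 libraries. Counts "adjusted over the list alone" use the members' edgeR p-values, adjusted within the list.

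The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule names 10 genes in any case (Prkcz, Prkci, Slc2a1, Slc2a2, Slc2a5, Slc5a1, Hk2, G6pc, Pck1 and Gcg). It then takes up to 12 genes per direction with the greatest change among those past the threshold, with a mean of at least 1 CPM and with group ranges that do not overlap. Where no gene passes, it takes the 12 per direction with the smallest p that meet the same conditions of level and range. These are given as not past the threshold. Gene models without a proper symbol and immunoglobulin or T cell receptor segments are left out. For a list past its threshold it takes up to 4 members with the smallest p in the list's direction, and for another list up to 2. Genes named outside the rule are said to be so, and 1 gene that the rule takes is not reported here.

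The alternatives were other scalings (DESeq2's size factors, upper quartile), other filters (none, a mean of at least 1 CPM), limma voom with sample quality weights, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), 1 surrogate variable from sva 3.50.0, other thresholds, the table without 758 rows of ribosomal RNA, mitochondrial genes and receptor segments, and leaving out each library in turn. The fits on protein-coding rows alone, and those with a marker score as a covariate, were chosen after seeing the data. The 10 splits of the 6 libraries into 3 against 3 were fitted in the same way.

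The edgeR and camera steps were tested on counts simulated for the 18456 genes from the libraries' means, depths and dispersions, in 5 draws. For the comparison of PKCzeta with GFP, the test recovered 1.2% of 250 genes changed 1.5-fold, 13.6% of those changed 2-fold, 81.2% of those changed 4-fold and 96.4% of those changed 8-fold. These genes were drawn from those with a mean of at least 1 CPM and counted over the 5 draws. Of them, 0 were called in the wrong direction. Of 530 calls, 43 (8.11%) were unchanged genes, above the 5% that the adjustment aims at. In camera with the preset correlation, a list shifted by -0.70 on the log2 scale passed in 5 of 5 draws. Over those draws 3 unshifted lists passed. Camera with an estimated correlation was not run on the simulated counts. The simulated genes vary independently, which real genes do not.

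Of 87 genes named in the text with a position, 5 overlap another gene whose counts come to at least 10% of theirs: Fam151a (Acot11), Lrrn4 (Crls1), Abcg8 (Abcg5), Rsc1a1 (Ddi2) and Pcx (Lrfn4). Since the use of strand in counting is not given, their values are uncertain. So are those of members of close families that can share reads, among them the H2-Q, Gbp, Hbb and Slc5a4 genes.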

Results

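Total RNA was sequenced from 6 samples of mouse small intestine. The 3 control libraries carry the label of a green fluorescent protein (GFP), and the other 3 carry that of overexpression of PKCzeta, an atypical protein kinase C encoded by Prkcz. The titles of all 6 libraries also begin with the letters DIO, which the sources used here do not explain. The stated aim was to find the genes that change with Prkcz overexpression, and the study's title names atypical PKC and GLUT1, the glucose transporter encoded by Slc2a1, in connection with gastric bypass. The total count was 85411847, 89895151 and 93742978 in GFP replicates 1-1, 1-4 and 3-1, and 86827885, 77573133 and 87572356 in PKCzeta replicates 2-1, 4-1 and 4-2. Pearson's r of log2 CPM across genes ran from 0.959 to 0.969 within groups (6 pairs) and from 0.953 to 0.977 between groups (9 pairs). The share of counts in mitochondrial genes was 9.08%, 3.37% and 10.7% in the GFP libraries and 9.19%, 5.67% and 2.92% in the PKCzeta libraries, in the same order.

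Prkcz was not higher in the libraries labelled PKCzeta overexpression. This gene (Entrez 18762) lies on chromosome 4 from 155260118 to 155361428 in mm10. Its level was 70.5, 98.6 and 96.9 CPM in the GFP libraries and 82.5, 100.07 and 57.0 CPM in the PKCzeta libraries, or 88.7 ± 15.8 against 79.9 ± 21.6 (SD, n = 3 each). The log2 fold change was -0.15 (SE 0.24, 95% interval -0.69 to 0.39), with an adjusted p of 0.950 in edgeR's quasi-likelihood test. The exact two-sided permutation p was 0.7, where 3 against 3 cannot give less than 0.1. Without PKCzeta replicate 4-2 the log2 fold change was 0.047, and on log2(TPM + 1) it was 0.053. Prkci, which encodes the other atypical PKC, had a log2 fold change of -0.012 (SE 0.15, edgeR adjusted p 0.993), and 0.19 on log2(TPM + 1). The median of all tested genes on log2(TPM + 1) was itself 0.21, so neither gene lay above it there. Since the targeted gene does not go with the labels, the groups are called GFP-labelled and PKCzeta-labelled, and every direction given here is a direction between labels.

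Slc2a1 stood at 11.04, 11.6 and 13.2 CPM in the GFP-labelled libraries and at 13.8, 11.2 and 21.0 CPM in the PKCzeta-labelled ones. The gene (Entrez 20525) lies on chromosome 4 from 119108745 to 119137330. The means were 11.95 ± 1.13 and 15.3 ± 5.11 CPM (SD, n = 3 each), a log2 fold change of 0.36 (SE 0.26, 95% interval -0.25 to 0.96) with an edgeR adjusted p of 0.917 and an exact two-sided permutation p of 0.3. PKCzeta replicate 4-2 carried the difference, and without it the log2 fold change was 0.064. The intestinal sugar transporters Slc2a2 (GLUT2), Slc2a5 (the fructose transporter GLUT5) and Slc5a1 (the sodium-glucose transporter SGLT1) had log2 fold changes of -0.74, -0.54 and -0.32, with SEs of 0.58, 0.43 and 0.34. G6pc and Pck1, enzymes of glucose production, had -0.72 (SE 0.60) and 0.33 (SE 0.97), the hexokinase gene Hk2 had -0.16 (SE 0.27) and the proglucagon gene Gcg had 0.049 (SE 0.23). The edgeR adjusted p of these 7 genes was 0.917 or more, and Pck1 had -1.37 without PKCzeta replicate 4-1.

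**Figure D1:**
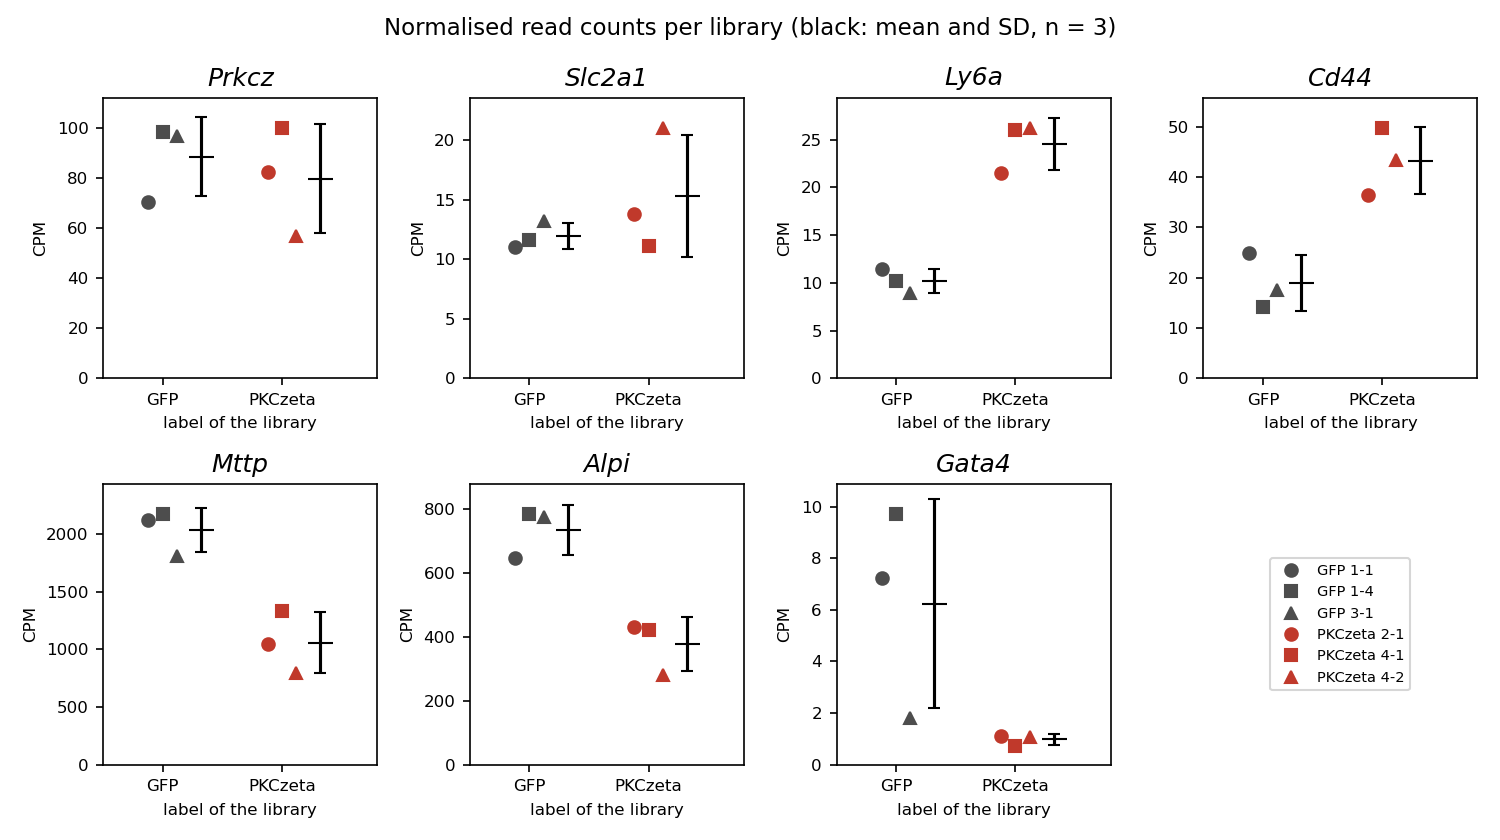
Normalised read counts (CPM, vertical axis from 0) of 7 genes in each of the 6 libraries, by label, with the mean and SD of each group in black (n = 3). The groups overlap for Prkcz (57.0 to 100.07 CPM with the PKCzeta label) and Slc2a1. They lie apart for Ly6a, Cd44, Mttp, Alpi and Gata4, none of which passed the adjusted threshold. For Ly6a and Cd44 that separation was a condition of their choice.

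The question of which genes change was tested over 18456 genes, and 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. The smallest adjusted p was 0.858. At an unadjusted p under 0.05 there were 1012 genes, 445 higher and 567 lower with the PKCzeta label, where 923 would be given by chance. The groups' ranges did not overlap for 1916 genes, or 10.4%, where chance gives 10%. DESeq2 called 82 genes, 44 higher and 38 lower, with 3963 adjusted p-values not given, while limma voom and limma on TPM values called 0.

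The genes that the rule takes for a small p are given next as not past the threshold. The rule asks for a mean of at least 1 CPM and for group ranges that do not overlap. Those with higher values under the PKCzeta label come first. Ly6a (Entrez 110454, chromosome 15 from 74994877 to 74998031), a surface antigen that is also induced by interferon, was at 10.2 ± 1.26 CPM with the GFP label and 24.5 ± 2.67 with the PKCzeta label (SD, n = 3), a log2 fold change of 1.27 (SE 0.19). Cd44, a receptor for hyaluronan, had 18.9 ± 5.53 against 43.2 ± 6.65 CPM (log2 fold change 1.19, SE 0.24). Il1rn, the interleukin-1 receptor antagonist, had a log2 fold change of 1.86 (SE 0.40), and Trem1, a receptor of neutrophils and monocytes, had 2.78 (SE 0.61) from a mean of 0.261 CPM. Gfap, a protein of glia, had 2.04 (SE 0.46), and the interferon-induced GTPase Gbp3 had 0.90 (SE 0.19). The others were Crispld2, Akap2, Akap12, Tubb6, Tnfrsf11b and Adam8, with log2 fold changes of 1.23, 1.19, 0.89, 1.11, 1.19 and 1.45. All 12 had an edgeR adjusted p of 0.858.

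Among the genes with lower values, Fam151a was at 63.5 ± 53.1 CPM with the GFP label and 2.47 ± 0.894 with the PKCzeta label (SD, n = 3), a log2 fold change of -4.69 (SE 0.76). Asah2, the neutral ceramidase of the brush border, was at 482 ± 151 against 172 ± 19.0 CPM (log2 fold change -1.49, SE 0.26). Abcg8, a part of the sterol exporter of enterocytes, had -1.08 (SE 0.22), and the nucleoside transporter gene Slc28a1 had -1.92 (SE 0.40). The others were Lrrn4, Fam3b, Gpm6a, Tsku, B4galt5, Rsc1a1 and Slc25a45, with log2 fold changes of -2.56, -0.74, -1.89, -2.08, -0.999, -4.35 and -1.38. All of these had an edgeR adjusted p of 0.858, and Fam151a, Lrrn4, Abcg8 and Rsc1a1 overlap other genes with counts that are not small beside theirs. DESeq2 called all of these higher and lower genes, but they were picked for a small p in the same counts, so this is no independent evidence.

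Of 49 gene lists, 25 passed an adjusted p of 0.05 in camera with the preset correlation, 17 lower and 8 higher with the PKCzeta label. With an estimated correlation 0 passed, and the smallest adjusted p was 0.210. This version passed 0 lists in any of the 10 splits of the 6 libraries, and its power was not simulated. The proximal small intestine list had an estimated correlation of -0.057, below the preset 0.01, yet camera's unadjusted p rose from 9.18e-07 to 0.00653. A list that fails in this version is therefore not shown to be unchanged. fry passed 2, the proximal small intestine list (lower) and the liver list (higher), each at an adjusted p of 0.0432. The median log2 fold change of all tested genes was 0.035, and 54.3% of them lay above 0. Scalings that use TPM moved this median to 0.21 and 0.24. With the enterocyte score as a covariate, 9 of the 25 calls remained in their direction. The calls that ended or turned there were those of polarity genes, xenobiotic metabolism, both MHC classes, both mitochondrial lists, the proximal list, interferon and cytokine genes, cholesterol synthesis, cell cycle, lymphoid cells, adipocytes, hexose transporters and gluconeogenesis, and that of enterocytes, which the covariate fixes because it is that list's own score. Of the 14 genes of that score, 1 is also in the hexose transporter list, 2 are in the proximal, 4 in the lipid and 5 in the brush border list, so these fits share members with their covariate. In limma voom the calls of gluconeogenesis, cholesterol synthesis, nuclear oxidative phosphorylation, cytokine, interferon, lymphoid and granulocyte genes ended (adjusted p 0.0688 to 0.298). The lists past the preset test are therefore described with the p from an estimated correlation, and their members by value. Adjusted over the list alone, 31 entries in 7 lists, or 28 different genes, passed 0.05, and over all genes 0.

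Genes of fat absorption stood lower together. In the list of lipid uptake and chylomicron assembly, 25 of 29 members were lower, with a median log2 fold change of -0.66, and 19 of them were past 0.05 adjusted over the list alone. Mttp, which loads lipid onto apolipoprotein B, was at 2034 ± 193 CPM with the GFP label and 1058 ± 267 with the PKCzeta label (SD, n = 3; log2 fold change -0.94, SE 0.23). Dgat2, an enzyme of triglyceride synthesis, had -0.70 (SE 0.17), the sterol exporter gene Abca1 had -0.89 (SE 0.23), and Abcg8 is given above. The list's score did not overlap between the groups, with 0.29, 0.43 and 0.29 in the GFP-labelled and -0.31, -0.077 and -0.63 in the PKCzeta-labelled libraries. The adjusted p was 4.02e-27 with the preset correlation, and the adjusted p was 0.210 with an estimated correlation.

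The digestive surface followed the same direction. All 28 tested members of the list of brush border enzymes and peptide transport were lower (median log2 fold change -0.64), and 2 were past 0.05 adjusted over the list alone. These were Alpi, the intestinal alkaline phosphatase, at 734 ± 77.1 against 377 ± 84.4 CPM (SD, n = 3), and Enpp7, the alkaline sphingomyelinase, at 531 ± 199 against 90.7 ± 71.7 CPM. The peptidase gene Ace had a log2 fold change of -1.18 (SE 0.41). All 14 enterocyte markers were lower as well (median -0.71), among them Krt20 at 1668 ± 89.5 against 1107 ± 72.1 CPM and Apoa4 at 1962 ± 1136 against 658 ± 173 CPM, and 11 of the 14 also stand in another list. The adjusted p was 7.57e-25 for the brush border and 9.44e-13 for the enterocyte list with the preset correlation, and the adjusted p was 0.312 and 0.305 with an estimated correlation. Enterocyte scores overlapped between the groups (0.56, 0.73 and 0.11 against -0.54, 0.16 and -1.02).

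Genes that mark the upper part of the small intestine were lower too. Of 13 tested members of the proximal list 11 were lower (median -0.47), with 3 past 0.05 adjusted over the list alone, namely Gata4, Gata6 and Apoa4. Gata4 (chromosome 14 from 63198914 to 63271712), a transcription factor of the duodenum and jejunum, was at 7.22, 9.70 and 1.79 CPM with the GFP label and 1.11, 0.738 and 1.08 CPM with the PKCzeta label, a log2 fold change of -2.67 (SE 0.58). Gata6 had -0.60 (SE 0.17) and Rbp2, the retinol-binding protein of enterocytes, had -1.07 (SE 0.42). The scores were 0.50, 0.42 and 0.15 against -0.36, -0.36 and -0.36. The distal list was also lower, in 15 of 17 members (median -0.30), with Muc13 at -0.72 (SE 0.23). The adjusted p was 6.43e-06 for the proximal and 3.56e-05 for the distal list with the preset correlation, and the adjusted p was 0.210 and 0.470 with an estimated correlation.

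Transport of sugars and bile acids gave lower values as well. In the list of hexose transporters 14 of 17 members were lower (median -0.50), and Slc5a4b and Slc5a9, of the sodium-glucose transporter family, were past 0.05 adjusted over the list alone, with -2.64 (SE 0.62) and -0.96 (SE 0.24). Slc2a9, a urate transporter, had -0.63 (SE 0.24). The 3 higher members of the list included Slc2a1, and 1 of the others had an unadjusted p under 0.05 in edgeR. With the enterocyte score as a covariate the list's median was -0.060 and camera's direction was higher (adjusted p 0.991). Of the bile acid list 6 of 8 members were lower (median -0.54), with the bile acid exporter genes Slc51a at -0.64 (SE 0.25) and Slc51b at -0.65 (SE 0.25), while the hormone gene Fgf15 varied from 6.27 to 118.5 CPM within the GFP-labelled libraries. The adjusted p was 0.000134 for hexose transporters and 0.00037 for bile acids with the preset correlation, and the adjusted p was 0.305 for each with an estimated correlation.

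Xenobiotic metabolism was lower in 28 of 37 members (median -0.36), with the carboxylesterase gene Ces2a at -0.98 (SE 0.27) and the exporter gene Abcc2 at -1.01 (SE 0.32). Tight and adherens junctions were lower in 21 of 24 (median -0.32), with the cadherin gene Cdh1 at -0.52 (SE 0.19) and the claudin gene Cldn4 at -1.02 (SE 0.38). Their estimated-correlation adjusted p was 0.386 each. The list of atypical PKC and the polarity complex was lower in 16 of 19 (median -0.15), with Pard6b at -0.94 (SE 0.26) and Mark2 at -0.41 (SE 0.15), an adjusted p of 0.00616 with the preset correlation and an adjusted p of 0.305 with an estimated correlation. Gluconeogenesis was lower in 12 of 16 (median -0.18), with Creb3l3 at -0.95 (SE 0.26) and Pcx at -0.55 (SE 0.17), and its adjusted p was 0.470 with an estimated correlation. Its call ended without GFP replicate 1-4 (adjusted p 0.0739) and without PKCzeta replicate 4-2 (adjusted p 0.176), and with the enterocyte score as a covariate the list stood higher (median 0.21, adjusted p 0.0147).

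Antigen presentation was lower in 13 of 15 members for MHC class I (median -0.46; H2-Q1 -0.76, SE 0.25, and H2-Q2 -0.89, SE 0.32) and in 6 of 8 for class II (median -0.52; H2-Ab1 -0.62, SE 0.27, and Cd74 -0.58, SE 0.29). In class I, 4 members were lower and 1 was higher at an unadjusted p under 0.05 in edgeR. The adjusted p of class I and class II was 0.470 and 0.531 with an estimated correlation. The class II call ended without PKCzeta replicate 4-2 (adjusted p 0.0578). Mitochondrially encoded mRNAs were lower in 11 of 13 (median -0.53; the mitochondrial COX2 -0.56, SE 0.46) and nuclear genes of oxidative phosphorylation in 35 of 40 (median -0.077; Cycs -0.30, SE 0.15), each with an adjusted p of 0.683 with an estimated correlation. The mitochondrial call ended without GFP replicate 1-1 (adjusted p 0.159), GFP replicate 3-1 (0.878) or PKCzeta replicate 4-2 (0.801), and the nuclear call without GFP replicate 1-4 (0.962) or PKCzeta replicate 2-1 (0.0945). Red cell genes were lower in 5 of 5 (median -1.57; Hbb-bs -1.67, SE 0.74) and adipocyte markers in 9 of 14 (median -0.29; Cidec -0.68, SE 0.31), with adjusted p of 0.460 and 0.570 with an estimated correlation. Red cell scores overlapped between the groups and were highest in GFP replicate 3-1 (2.03, against -1.67 to 0.31 in the other libraries). The adipocyte call ended without PKCzeta replicate 4-2 (median 0.090, adjusted p 0.801).

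**Figure D2:**
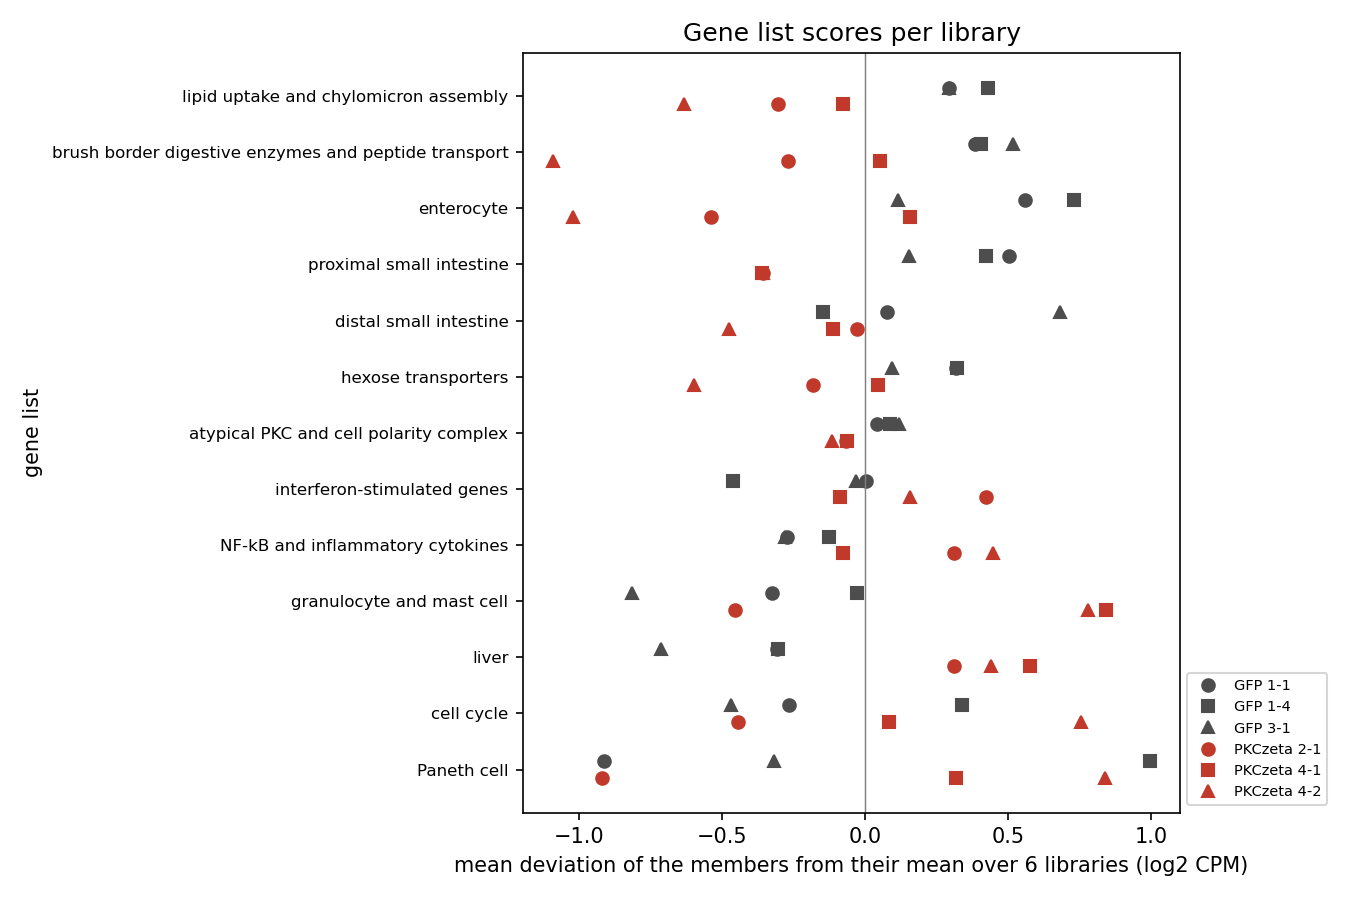
Score of 13 gene lists in each library, as the mean deviation of the members from their mean over the 6 libraries (horizontal axis, log2 CPM), with GFP-labelled libraries in grey and PKCzeta-labelled ones in red. The lipid scores of the PKCzeta-labelled libraries (-0.63 to -0.077) all lie below those of the GFP-labelled ones (0.29 to 0.43), while the Paneth cell and cell cycle scores cross the groups.

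Of 42 interferon-stimulated genes 32 were higher (median 0.22), led by the GTPase genes Gbp2 (29.2 ± 3.05 against 96.8 ± 61.6 CPM, SD, n = 3) and Gbp5 (log2 fold change 1.81, SE 0.47). Of 37 NF-kB and cytokine genes 24 were higher (median 0.19, mean 0.55), with the acute-phase gene Saa3 at 1.42 ± 0.121 against 13.1 ± 13.2 CPM, the neutrophil attractant gene Cxcl5 at a log2 fold change of 2.68 (SE 0.72) and the cytokine gene Il22 at 4.02 (SE 1.11) from a mean of 0.0443 CPM. At an unadjusted p under 0.05 in edgeR, 7 members of the cytokine list were higher and 2 were lower. Granulocyte and mast cell genes had a median of 0.064 and a mean of 0.82, and only 7 of 13 were higher. The 4 members with the smallest p were genes of neutrophils, S100a8 (1.07 ± 0.716 against 8.42 ± 6.61 CPM), S100a9, Csf3r and Cxcr2, with p adjusted over the list alone of 0.0587 to 0.0698 in edgeR. Their higher values lay mainly in PKCzeta replicates 4-1 and 4-2, and the neutrophil granule gene Ltf, chosen after its values were seen, had a log2 fold change of -0.043 (SE 0.33). The adjusted p of the 3 lists was 0.00179, 0.0179 and 0.0294 with the preset correlation, and the adjusted p was 0.584, 0.444 and 0.570 with an estimated correlation. The interferon call ended without GFP replicate 1-4 (adjusted p 0.2998) or PKCzeta replicate 2-1 (0.261). The cytokine call ended without any of GFP replicates 1-1 and 1-4 and PKCzeta replicates 2-1 and 4-2 (adjusted p 0.0566 to 0.145) and among genes with a mean of at least 1 CPM (median 0.13, adjusted p 0.111). The granulocyte call ended without GFP replicate 1-1 or PKCzeta replicates 4-1 or 4-2 (adjusted p 0.0794 to 0.204) and with the Paneth cell score as a covariate (0.167).

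Liver markers were higher in 9 of 11 (median 0.21, mean 0.86), led by the fibrinogen genes Fgb (0.0763 against 0.755 CPM) and Fga (0.258 against 0.899 CPM) and by Serpina3k, all at low levels. The list's adjusted p was 0.00616 with the preset correlation and the adjusted p was 0.305 with an estimated correlation, and its call ended without GFP replicate 1-1 (adjusted p 0.0592) and among genes with a mean of at least 1 CPM (adjusted p 0.0520). Enteric neuron and glia markers were higher in 14 of 17 (median 0.56), with Gfap past 0.05 adjusted over the list alone, and T and innate lymphoid markers in 18 of 23 (median 0.63; Cd3d 1.06, SE 0.56, and 1.70 without GFP replicate 1-1 and 0.43 without PKCzeta replicate 2-1). Their adjusted p was 0.470 and 0.662 with an estimated correlation. The former call ended without PKCzeta replicate 4-1 (adjusted p 0.0710) and the latter without GFP replicate 1-4 (0.213) or PKCzeta replicate 2-1 (0.530). Cholesterol synthesis was higher in 17 of 25 (median 0.27; Fdps 0.49, SE 0.15, and Hmgcs1 0.38, SE 0.17), with an adjusted p of 0.661 with an estimated correlation, and its call ended without GFP replicate 1-4 (adjusted p 0.574) or PKCzeta replicates 2-1 (0.530) or 4-1 (0.0836). All 36 cell cycle genes were higher (median 0.29; Ccnd2 0.29, SE 0.21), with an adjusted p of 0.683 with an estimated correlation, and its call ended without GFP replicates 1-1 (adjusted p 0.135) or 3-1 (0.467). Without PKCzeta replicate 4-2 the direction turned (median -0.048, adjusted p 0.456).

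The other 24 lists did not pass, with adjusted p from 0.0712 for B and plasma cells to 0.986. Among Wnt targets (median 0.11, adjusted p 0.317), Cd44 was past 0.05 adjusted over the list alone. The Paneth cell list had a median of 0.038 and an adjusted p of 0.623, and crossed the groups library by library. For antimicrobial peptides the median was -0.093 and the mean 0.077, for the other protein kinase C genes -0.035 and 0.098, and for enteroendocrine cells both were above 0 (0.015 and 0.040), while camera's direction was lower for these 3 lists.

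The same fits were made for each of the 10 ways to divide the 6 libraries into 3 against 3. The labelled groups gave 25 lists past the preset test, and the 9 other divisions gave from 10 to 21. The division of GFP replicates 1-1 and 3-1 and PKCzeta replicate 2-1 against the rest gave 3170 genes at an unadjusted p under 0.05 in edgeR, where the labelled groups gave 1012.

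**Figure D3:**
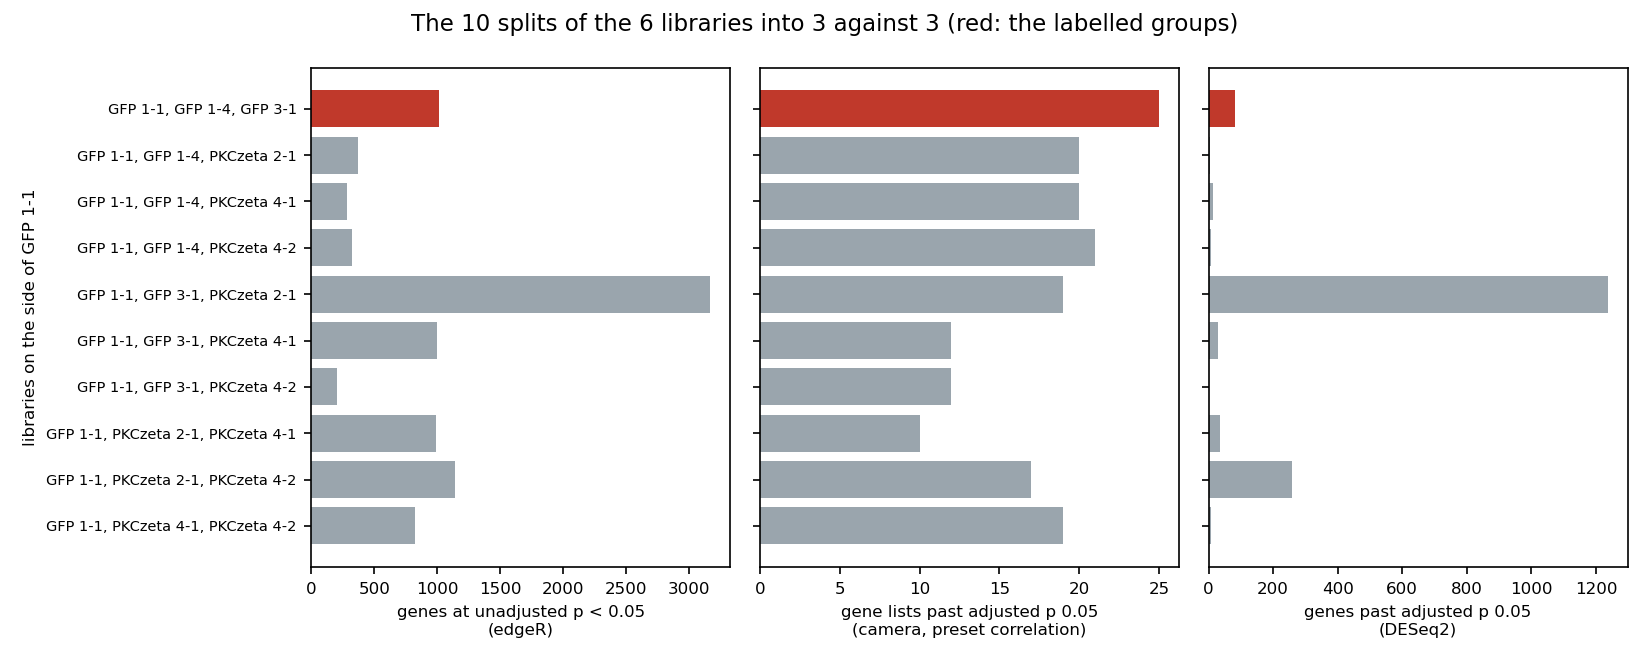
Genes at an unadjusted p under 0.05 in edgeR (left), lists past an adjusted p of 0.05 in camera (middle) and genes past an adjusted p of 0.05 in DESeq2 (right) in each of the 10 divisions of the 6 libraries, named by the side that holds GFP replicate 1-1, with the labelled groups in red. The labelled groups had the most lists (25, with 21 next), while another division had the most genes in both tools (3170 in edgeR, 1236 in DESeq2).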

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

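Fits on protein-coding rows and with a marker score as covariate were chosen after seeing the data; all else was planned. The count of 0 genes past the threshold held in edgeR under every scaling and filter tried, with 1 surrogate variable, with either marker score, with each library left out, and in limma voom and limma on TPM. It became 82 with DESeq2 and 414 (270 higher, 144 lower) at an unadjusted p under 0.05 with a fold of at least 2, where the looser threshold is the cause. Lists past the preset test numbered 25, 21 to 26 with a library left out, 0 with an estimated correlation, 2 with fry and 13 with the enterocyte score as covariate, where 9 of the 25 kept their call and direction. limma voom kept 18 of 25. Of the values of named genes under the alternatives, 1587 stayed on the same side of the threshold in the same direction, 24 turned in direction and 36 came past the threshold, in DESeq2. The cause of the other changes was not tested.

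The log2 fold change of Prkcz ran from -0.35 to 0.047 with a library left out and was 0.053 and 0.055 on the TPM scales and 0.24 with the enterocyte score. That of Slc2a1 ran from 0.064 to 0.54, and was -0.31 with the enterocyte score. With a library left out, Prkci ran from -0.10 to 0.018, Hk2 from -0.49 to 0.056, Pck1 from -1.37 to 0.88, Ltf from -0.24 to 0.13 and Gcg from -0.13 to 0.26, and the median of the cell cycle list from -0.048 to 0.63, of Wnt targets from -0.24 to 0.41 and of the Paneth cell list from -0.38 to 0.80. In the same fits Slc2a2 ran from -1.58 to -0.37, Slc2a5 from -0.82 to -0.20, Slc5a1 from -0.77 to -0.062, G6pc from -1.17 to -0.32, Fgf15 from -3.16 to -0.85, Hbb-bs from -2.33 to -0.60, Cidec from -0.92 to -0.29, COX2 from -0.99 to -0.19, Cd3d from 0.43 to 1.70, Ccnd2 from 0.10 to 0.42, Fga from 1.35 to 2.84 and Serpina3k from 1.26 to 5.27. On log2(TPM + 1) and log2(TPM + 0.1), Prkci had 0.19 and 0.20 and Pck1 -0.28 and -0.30, and G6pc had 0.049 in limma voom. The medians of all tested genes on those TPM scales were 0.21 and 0.24, above the values of Prkcz and Prkci there. With the enterocyte score as covariate, Slc2a2 had 0.88, Slc2a5 0.74, Slc5a1 0.53, G6pc 0.84, Gcg -0.023, Rbp2 0.22 and Cidec 0.029, and the lists whose direction turned had medians of -0.060 (hexose transporters), 0.21 (gluconeogenesis), -0.19 (Wnt targets), 0.098 (adipocyte) and -0.19 (enterocyte, fixed by the covariate, which is that list's own score and includes Slc5a1). With the Paneth cell score as covariate, the Paneth cell median was -0.035, fixed in the same way. That list passed without GFP replicate 1-4 or PKCzeta replicate 2-1. At 77573133 counts or more per library, depth limits mainly genes far below 1 CPM, such as Fgb and Il22.

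The titles give each library 2 numbers, whose meaning is not given. The first is 1, 1 and 3 in the GFP-labelled libraries and 2, 4 and 4 in the PKCzeta-labelled ones. The second is 1, 4 and 1 against 1, 1 and 2. No pairing of the groups is stated, so no paired analysis was made. The first number is shared within each group but not between them. If it names a shared origin of samples, that origin could not be told apart from the label, and n = 3 would overstate the independent samples.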

Other observations

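The tests here were chosen after the results they bear on were seen, except the count of genes that DESeq2 calls in the other divisions of the libraries.

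Markers of the mesothelium, the cell layer that covers the outer gut wall, were lower with the PKCzeta label. The list was drawn up after Lrrn4 and Gpm6a had appeared among the genes with the smallest p, so its first 5 members (5 of 5 lower, median log2 fold change -1.89) are no independent evidence. Of 8 further members written down without knowledge of their values, 8 were lower (median -1.48), and 4 were past 0.05 adjusted over the list alone. These 8 mark the same cell layer in the same libraries, so they are not independent of the members seen first. Their p-values are those of a cell type picked from these data. Muc16 was at 3.91 ± 2.64 against 0.559 ± 0.301 CPM and Pkhd1l1, chosen like it after the values were seen, at 4.47 ± 2.21 against 1.11 ± 0.426 CPM (SD, n = 3), and the list's unadjusted p was 0.033 in limma's camera with an estimated correlation. Upk1b and Aldh1a2, the most abundant of the 8, had -0.59 (SE 0.24; 14.1 against 9.38 CPM) and -0.57 (SE 0.31; 6.31 against 4.26 CPM). A list of genes of epithelial repair, drawn up in the same way because of Ly6a, had 14 of 22 members higher (median 0.29). Its unadjusted p in limma's camera was 0.128 with the preset correlation and 0.170 with an estimated correlation.

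For the count of genes and of lists, 3 against 3 allows 10 divisions, which are too few for a share under 0.05. For genes past an adjusted p of 0.05 in edgeR the labelled groups gave 0 and the highest other gave 1; since no count lies below 0, 10 of the 10 must give as many, and this count says nothing about the grouping. At an unadjusted p under 0.05, 3 of the 10 gave as many as the labelled groups (1012, highest other 3170). For lists past the preset test it was 1 of 10 (25, highest other 21), and for genes called by DESeq2 3 of 10 (82, highest other 1236). With an estimated correlation, 0 lists passed in any division.

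Prkcz was not higher with the label that names its overexpression. A transcript of the vector that is counted as Prkcz and raises it at least 2-fold, a size chosen here, is argued against by the upper bound of the 95% interval, 0.39 on the log2 scale. Exchanged group labels with such a transcript are argued against by the lower bound, -0.69. A vector transcript that is not counted as Prkcz, for instance from a cDNA of another species, may still be there. A search for GFP, a transgene or a vector found 1 name, that of the mouse gene Mpv17l, and so 0 rows for a vector, which leaves this open, as are a rise confined to few cells and a label that does not hold for the RNA.

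Enterocyte and lipid absorption genes stood lower with the PKCzeta label, and PKCzeta replicate 4-2, which has the lowest scores, does not set the lipid difference alone, since without it the score difference was -0.53 (SE 0.12). A smaller share of enterocytes in the samples could give the pattern, and cannot be told apart from a change within these cells, because of 14 lists of other cell types of the gut wall 8 stood higher and 6 lower, none of these 14 by more than 2 SE. Left out of the 14 were the liver (score difference 0.88, SE 0.16), pancreas (0.34, SE 0.35) and red cell lists (-1.37, SE 0.87), and the mesothelium list without its first members stood lower (-1.32, SE 0.51), a cell type picked because some of its genes had been seen to be lower. A more distal piece of intestine is a further candidate source and stays open. The proximal score was lower (difference -0.72, SE 0.11), as it would need. The distal score, which should be higher, was not (-0.41, SE 0.28). It was highest in GFP replicate 3-1 (0.68, against -0.47 to 0.077 in the other libraries). Relative to the enterocyte score both differences were within 2 SE of 0 (proximal 0.22, SE 0.36, and distal 0.53, SE 0.51). That comparison cannot decide, since 2 of the 14 enterocyte markers are also in the proximal list. Whether the other markers differ by region was not tested. An effect of PKCzeta itself was not tested apart from these candidate sources, since the label and these differences coincide and Prkcz gave no check of the label.

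The division of GFP replicates 1-1 and 3-1 and PKCzeta replicate 2-1 against the rest points to a structure of the samples that crosses the labels. Different shares of crypt epithelium may underlie it: over the 6 libraries the Paneth cell and cell cycle scores had a Pearson r of 0.874 (exact permutation p 0.0389, adjusted over 3 relations 0.0389) and a Spearman rho of 0.771 (exact permutation p 0.103, adjusted 0.103), and r was 0.859 without GFP replicate 1-4 and PKCzeta replicate 2-1. A different recovery of structured noncoding RNA could as well, since the Paneth cell score and the share of counts in Rn7s1, Rn7s2, Rn7sk and Rpph1 had an r of -0.952 (exact permutation p 0.0181, adjusted 0.0389) and a rho of -0.886 (exact permutation p 0.0333, adjusted 0.1), with an r of -0.903 without those 2 libraries. The mitochondrial mRNA score had an r of -0.886 with the Paneth cell score (exact permutation p 0.0319, adjusted 0.0389; rho -0.771, exact permutation p 0.103, adjusted 0.103; r -0.847 without the 2 libraries). Unlike the Paneth cell and cell cycle scores, the intestinal stem cell score did not follow the division. It was 0.025 in GFP replicate 1-1 and -0.0024 in GFP replicate 3-1, above -0.071 in PKCzeta replicate 4-1. The explanations by crypt share and by recovery of noncoding RNA both stay open. None of the adjusted p-values for rho passed 0.05, and within a group of 3 no r was computed. The share of counts in rows of ribosomal RNA divided the libraries in the same way. It was at least 4.4013% in GFP replicates 1-1 and 3-1 and PKCzeta replicate 2-1, and at most 2.3294% in the rest. The protein-coding share was at most 85.007% on that side and at least 88.564% in the rest. Whether the ribosomal RNA share underlies the division was not tested, so it stays open too.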
